A study of Mus musculus with 8 samples.

How the data were processed

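Expression was measured on Illumina MouseRef-8 BeadChips, which read each transcript with bead-bound probes of 1 sequence each, in bone marrow-derived macrophages of C57BL/6 mice. The labels' protocols state that marrow cells were grown in 30% conditioned medium of L929 cells, a source of the macrophage growth factor M-CSF, replated on day 7 in 15% conditioned medium and stimulated on day 8 for 6 h. The stimuli were interferon gamma (IFNγ, 10 ng/ml), sheep red blood cells coated with a mouse IgG2a antibody at 10 red cells per macrophage, or both. Total RNA was extracted, treated with DNase, amplified and labelled with biotin, per the labels' protocols. Each of the 4 groups has 2 arrays, 8 in all, and groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical.

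The values used are the deposited intensity values of 25697 probes on a linear scale, made by the authors with GenomeStudio, per the submitters' processing notes. Its version and the normalization method are not given in the sources used here. From the values, the arrays had been quantile normalized: sorted, the 8 columns differed by at most 0.961% at any rank. The lowest deposited intensity was 119.8 and the most frequent about 172, so background had not been subtracted and fold changes of dim genes are understated. A further deposited table of intensity and detection p-values was not used here, because none of its 16 per-sample columns (8 of signal and 8 of detection p-values) has a name that matches a sample's labels.

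Before the data were examined, the plan was limma's neqc background correction with detection p-values. The intensities above needed another route, so the main test was limma on log2 of the deposited intensity, with no further background correction or normalization. Probes were kept when they lay above a background floor on both arrays of at least 1 group. The floor was set after the data were seen, at the mode of all log2 values plus 1.64 times the SD of the values below the mode, an intensity of 200.1, in place of the planned detection p under 0.05. A group counted as not above background for a gene when neither array passed the floor. In that case a change is given as "at least N-fold", the brighter group's mean against the higher of the floor and the dim probe's own signal. After the filter 12316 probes remained (47.9%).

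The array's annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719, and 23962 Entrez identifiers were found in the reference gene table, with 0 symbols updated. Each gene was represented by its brightest probe over the 8 arrays, and probes without a symbol stayed as features of their own, which gave 9341 features (8620 named). Where probes of a named gene moved in opposite directions, the text says so. Probes that moved the same way by a smaller amount are mostly not listed. For example, Cd40 with IFNγ ranged from 0.31 to 4.54 over 4 probes, and Ednrb with opsonised cells from 0.18 to 2.37 over 3.

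limma 3.58.1 in R 4.3.3 fitted all 8 arrays with 4 group means (lmFit, then eBayes with an intensity trend; 4 residual degrees of freedom, 22.6 in total after moderation), and Benjamini-Hochberg adjustment was applied within each comparison with a threshold of 0.05. The 6 contrasts were each stimulated group against unstimulated cells, both stimuli against each single stimulus, and the interaction, which is the log2 change made by opsonised cells in the presence of IFNγ minus that in its absence. A positive interaction means a level with both stimuli above the sum of the single log2 changes. Values after ± are standard errors of the fitted log2 change, with 2 arrays per group, and adjusted p-values are limma's. Genes above or below both single stimuli were those passing both tests of the combination against a single stimulus with the same sign.

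Gene lists were fixed before the data were examined. They cover IFNγ target genes, MHC class II presentation, MHC class I presentation with the immunoproteasome, type I interferon-responsive antiviral genes, inflammatory cytokines with NF-κB targets, anti-inflammatory regulators, immediate early and ERK or NFAT feedback genes, Fcγ receptors with ITAM signalling, the IFNγ receptor pathway, heme and iron handling, the NRF2 oxidative stress response, lysosome and phagosome, cholesterol biosynthesis and uptake, LXR targets, cell cycle, glycolysis with HIF1 targets, endoplasmic reticulum and amino acid stress, alternative activation, macrophage identity, heat shock and housekeeping controls. Markers of neutrophils, erythroid cells, T and NK cells, B cells, dendritic cells, mast cells with basophils, and fibroblasts were added as lists of other cell types. Of the 28 lists, 24 had at least 2 tested members and entered limma's camera test with a preset correlation of 0.01 (144 tests over 6 contrasts, adjusted together), which asks whether members rank above or below the other genes. camera was repeated with an estimated correlation, and fry, which tests whether members move on balance one way, was also run.

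Named genes followed a rule fixed beforehand: the 10 largest changes in each direction for each stimulated group against unstimulated cells and for the interaction, the 6 largest for the other contrasts and for genes above or below both single stimuli, up to 2 called members per direction of each list, and a fixed set that includes the receptors of both stimuli. For a comparison of groups, both arrays of one group had to lie above both of the other. Uncharacterised loci were passed over. Of the fixed set, Il12b is not analysed here, since no probe used here carries its name, and Il6 and Il10 were not above background in any group.

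The scripts were tested on simulated data with 9341 genes, of which 200 were changed. For IFNγ against unstimulated cells, 92.5% of 1.5-fold changes and 100% of 2-fold and 4-fold changes were recovered. For opsonised cells the values were 94% and 100%. For the interaction, 55.2% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes were recovered, so smaller departures from additivity are often missed.

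Alternatives planned beforehand and run were no filter, every probe tested, no intensity trend, array weights, the compared groups alone, a replicate block, stricter thresholds and leaving out each array. Added after seeing the data were normexp background correction of the deposited intensities with offsets of 16 and 50, other background floors, cyclic loess, centring on the housekeeping list, and a correlation of the single responses with 1 control array each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.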

Results

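Transcript levels were measured in mouse bone marrow-derived macrophages that were left unstimulated or stimulated for 6 h with IFNγ, with IgG2a-coated sheep red blood cells (opsonised cells, a particle taken up through Fcγ receptors), or with both, with 2 arrays per group. The design asks how macrophages respond when the IFNγ receptor and the IgG receptor FcγRI are engaged together. The number of arrays limits the precision. Arrays of the same group correlated at 0.992 to 0.994 over all probes and arrays of different groups at 0.952 to 0.984. The first principal component (64.2% of the variance) separated the 4 arrays with IFNγ from the 4 without it, and the second (21.3%) separated arrays with and without opsonised cells.

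IFNγ alone raised the CXCR3-ligand chemokine genes Cxcl9 (at least 101-fold, adjusted p = 1.5e-23) and Cxcl10 (log2 change 6.29 ± 0.11, 78.1-fold), with 2 arrays per group. The guanylate-binding protein genes Gbp2 (5.36 ± 0.10) and Gbp3 (4.53 ± 0.10) and the immunity-related GTPase genes Igtp (4.74 ± 0.11) and Ifi47 (4.11 ± 0.12) rose as well. So did the costimulatory receptor gene Cd40 (4.54 ± 0.11) and the antiviral gene Ifit2 (4.12 ± 0.12). Upp1, which encodes a uridine phosphorylase, rose at least 22.9-fold and Calhm6 by 4.28 ± 0.11. The largest decreases were those of Lhfpl2 (-2.91 ± 0.10), the sialyltransferase gene St6gal1 (-2.21 ± 0.13) and the serotonin receptor gene Htr2b (-2.05 ± 0.12). Arap3 (-1.96 ± 0.12) and the iron exporter gene Slc40a1 (-1.82 ± 0.09) followed. The chemokine receptor gene Cxcr4 (-1.68 ± 0.13), the isocitrate dehydrogenase gene Idh1 (-1.65 ± 0.11), Ypel3 (-1.64 ± 0.11), the chemokine gene Ccl3 (-1.63 ± 0.11) and Zdhhc14 (-1.62 ± 0.12) also fell.

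Of 16 tested IFNγ target genes 15 rose with IFNγ (15 adjusted over the list alone; median 3.17, camera adjusted p = 1.75e-41). Among them were the transcription factor genes Irf1 (3.27 ± 0.10) and Irf8 (1.98 ± 0.14) and the feedback inhibitor gene Socs1 (at least 1.75-fold). Of 8 MHC class II genes 7 rose (7 over the list alone), led by H2-DMa (2.11 ± 0.11) and Cd74 (1.97 ± 0.12). The class II transactivator gene Ciita rose at least 2.77-fold. Of 14 MHC class I and immunoproteasome genes 12 rose (13 over the list alone), led by Nlrc5 (2.47 ± 0.12) and the peptide transporter gene Tap1 (2.31 ± 0.12). Of 16 type I interferon-responsive genes 15 rose (15 over the list alone; median 1.32), Isg15 by 3.19 ± 0.14. Its camera call was lost at an adjusted p = 0.0661 with an estimated correlation. Among anti-inflammatory regulators 7 of 10 rose (7 over the list alone), including the cytokine signalling suppressor gene Socs3 (3.98 ± 0.11) and Cd274, which encodes PD-L1 (3.84 ± 0.10). The phosphatase gene Dusp1 fell (-1.41 ± 0.12). Of 11 glycolysis and HIF1 target genes 6 rose (7 over the list alone), led by Pfkp (1.77 ± 0.13) and the glucose transporter gene Slc2a1 (1.20 ± 0.11).

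Other groups moved less evenly with IFNγ. Of 16 inflammatory cytokine and NF-κB target genes 7 rose and 2 fell (8 and 3 over the list alone). Tnf rose by 2.74 ± 0.11, Nos2 at least 1.20-fold, and Ccl4 fell by 0.53 ± 0.10. This list had an adjusted p = 0.0661 with an estimated correlation. Of 13 cholesterol biosynthesis and uptake genes 8 fell (9 over the list alone), for example Stard4 (-0.97 ± 0.12) and Mvd (-0.85 ± 0.12). The list had an adjusted p = 0.0661 with an estimated correlation. Of 13 heme and iron genes 5 fell and 1 rose (6 and 1 over the list alone). Hmox1, the heme-degrading oxygenase gene, was at -1.34 ± 0.10 (adjusted p = 0.0941 with an estimated correlation). Of 11 NRF2 genes 4 fell (4 over the list alone), Srxn1 by 1.29 ± 0.12 and Gclm by 0.68 ± 0.12 (adjusted p = 0.163 with an estimated correlation). Of 11 endoplasmic reticulum and amino acid stress genes 6 rose (6 over the list alone), Chac1 by 1.30 ± 0.12 and Atf3 by 1.04 ± 0.13 (adjusted p = 0.0931 with an estimated correlation). Of 19 cell cycle genes 8 fell and 1 rose (10 and 1 over the list alone). The cyclin D1 gene Ccnd1 was at 1.66 ± 0.12 and Cdk1 at -0.55 ± 0.11 (adjusted p = 0.135 with an estimated correlation).

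The receptors of the stimuli were themselves changed by IFNγ. Fcgr1, which encodes FcγRI, rose by 2.25 ± 0.11, Fcgr4 by 2.48 ± 0.10 and Fcgr3 by 1.02 ± 0.10. The inhibitory receptor gene Fcgr2b (0.12 ± 0.12) and the shared γ-chain gene Fcer1g (0.07 ± 0.08) did not pass the test, but Fcer1g stood so near the highest intensity on the arrays that a ceiling may hide a change. In the Fcγ receptor and ITAM list 5 of 12 genes rose and 1 fell (5 and 2 over the list alone). Tyrobp was at -0.63 ± 0.11, and the list had an adjusted p = 0.0871 with an estimated correlation. The IFNγ receptor gene Ifngr1 fell by 0.91 ± 0.11, and Ifngr2 was at -0.08 ± 0.12 without a call. In the receptor pathway list 4 of 8 genes rose and 1 fell (4 and 1 over the list alone), Stat3 by 1.74 ± 0.11 (adjusted p = 0.0773 with an estimated correlation). Over all 9341 features IFNγ raised 884 and lowered 1153, of which 241 and 77 changed at least 2-fold. With cyclic loess the split was 1008 higher and 836 lower (54.7% higher against 43.4%). Centring on housekeeping genes left 652 calls (334 higher, 318 lower), and the fit without IFNg replicate 2 gave 1291.

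Opsonised cells alone raised the heat shock gene Hspa1a (at least 12.3-fold, adjusted p = 2.0e-16) and Hmox1 (3.40 ± 0.10, 10.6-fold), with 2 arrays per group. Genes of glutathione supply and peroxide defence followed: the cystine transporter gene Slc7a11 (3.34 ± 0.12), Gclm, which encodes a subunit of the glutathione-synthesising glutamate-cysteine ligase (3.14 ± 0.12), and the sulfiredoxin gene Srxn1 (3.07 ± 0.12). The glutathione transferase gene Gsta3 rose by 2.55 ± 0.16. Dnmt3l (3.38 ± 0.12), Plpp3 (2.80 ± 0.13), the Mincle gene Clec4e (2.53 ± 0.12) and the endothelin receptor gene Ednrb (2.37 ± 0.12) were the other large increases. The transferrin receptor gene Tfrc fell most (-1.97 ± 0.12), followed by the RNA-binding protein gene Zfp36l1 (-1.55 ± 0.10) and Slco2b1 (-1.44 ± 0.13). Next were Zdhhc14 (-1.20 ± 0.12) and the circadian transcription factor gene Dbp (-1.13 ± 0.12). Acss1, Sesn1, Fgd2, Slc46a3 and Stard8 fell by between 1.12 and 1.02.

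Of 11 tested NRF2 genes 10 rose with opsonised cells (10 adjusted over the list alone; median 0.72, camera adjusted p = 1.18e-20). Of 13 heme and iron genes 7 rose and 2 fell (8 and 2 over the list alone). Spic, a transcription factor gene of iron-recycling macrophages, was at 2.37 ± 0.12 and the biliverdin reductase gene Blvra at -0.46 ± 0.11. Of 7 heat shock genes 5 rose (6 over the list alone), including Hsph1 (0.94 ± 0.12). Of 16 inflammatory genes 8 rose and 0 fell (8 over the list alone), among them the chemokine genes Cxcl2 (2.27 ± 0.12) and Cxcl1 (1.76 ± 0.12) and Tnf (1.53 ± 0.11). Of 10 anti-inflammatory regulators 6 rose (6 over the list alone), including Dusp1 (0.97 ± 0.12) and Cd274 (1.02 ± 0.10). Of 19 cell cycle genes 9 fell (13 over the list alone; median -0.37), Mcm4 by 0.76 ± 0.11 and Birc5 by 0.58 ± 0.11. All 6 of these lists kept their camera call with an estimated correlation.

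Of 16 IFNγ target genes 6 rose with opsonised cells (7 over the list alone): the adhesion molecule gene Icam1 by 1.47 ± 0.12, Gbp2 by 1.26 ± 0.10 and Cxcl10 by 1.10 ± 0.11. The list's call was also kept with an estimated correlation (adjusted p = 0.032). Of 16 type I interferon-responsive genes 6 rose (9 over the list alone), Rsad2 by 1.29 ± 0.15, with an adjusted p = 0.187 with an estimated correlation. Of 14 MHC class I genes 4 rose (5 over the list alone), H2-D1 by 0.56 ± 0.15 (adjusted p = 0.112 with an estimated correlation). Among MHC class II genes 0 of 8 passed (0 over the list alone; median -0.14). Of 13 cholesterol biosynthesis genes 8 rose (8 over the list alone), Cyp51 by 0.76 ± 0.13 and Mvd by 0.57 ± 0.12, with an adjusted p = 0.0515 with an estimated correlation. Of 11 endoplasmic reticulum and amino acid stress genes 4 rose (4 over the list alone), Atf3 by 1.19 ± 0.13 (adjusted p = 0.129 with an estimated correlation). The Fcγ receptor genes fell: Fcgr4 by 0.61 ± 0.10, Fcgr1 by 0.57 ± 0.11, Fcgr3 by 0.55 ± 0.10 and Fcgr2b by 0.42 ± 0.12. Altogether 5 of 12 list members were lower (5 over the list alone). That list had an adjusted p = 0.128 with an estimated correlation, and its median of -0.08 became 0.02 after centring on housekeeping genes. Ifngr1 fell by 0.56 ± 0.11.

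Over all features opsonised cells raised 565 and lowered 576, of which 76 and 11 changed at least 2-fold. Centring on housekeeping genes left 216 calls (191 higher, 25 lower), and the fits without unstimulated replicate 1 and without unstimulated replicate 2 gave 642 and 670. IFNγ and opsonised cells raised 146 genes in common and lowered 300, against 53.5 and 71.1 for independent lists of these sizes. A further 142 genes moved in opposite directions (50 up with IFNγ and down with opsonised cells, 92 the reverse). Across genes, which are not independent replicates, the log2 changes correlated at r = 0.246 (Spearman 0.353). Simulated unchanged groups that share the control arrays gave a mean r of 0.5 and a covariance of 0.00664, against an observed covariance of 0.0314. With 1 control array for each comparison, so that no array is shared, r was 0.184 and 0.187 and the covariance 0.0248 and 0.0252. Part of the overlap of calls above may come from the shared controls.

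Both stimuli together raised Cxcl9 at least 149-fold, Cxcl10 by 6.66 ± 0.11, Cd40 by 5.82 ± 0.11 and Gbp2 by 5.44 ± 0.10 relative to unstimulated cells (2 arrays per group). Upp1 rose at least 36.1-fold and Batf2, a transcription factor gene, at least 23-fold. Calhm6 (4.74 ± 0.11), Gbp3 (4.61 ± 0.10), the activation marker gene Cd69 (4.45 ± 0.11) and Igtp (4.42 ± 0.11) completed the 10 largest increases. St6gal1 (-2.85 ± 0.13), Lhfpl2 (-2.60 ± 0.10), Ypel3 (-2.54 ± 0.11), Zdhhc14 (-2.50 ± 0.12), Sesn1 (-2.48 ± 0.11), the costimulatory receptor gene Cd28 (-2.46 ± 0.13) and Tfrc (-2.45 ± 0.12) fell most. Lpar6 (-2.25 ± 0.12), Arhgap24 (-2.21 ± 0.12) and Sla (-2.08 ± 0.12) followed.

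Of 16 inflammatory genes 13 rose with both stimuli and 0 fell (13 over the list alone; median 1.38). Tnf stood at 3.85 ± 0.11, Ccl5 at 4.17 ± 0.13 and Nos2, the inducible nitric oxide synthase gene, at least 3.41-fold higher. Of 19 cell cycle genes 16 fell and 1 rose (16 and 1 over the list alone; median -1.20). The mitotic activator gene Cdc20 fell by 1.63 ± 0.12 and the replication helicase gene Mcm4 by 1.60 ± 0.11, while Ccnd1 stayed higher (0.53 ± 0.12). The IFNγ target genes (15 of 16 higher, 15 over the list alone) and MHC class II genes (7 of 8, 7 over the list alone) rose. So did MHC class I genes (13 of 14, 14 over the list alone), anti-inflammatory regulators (7 of 10, 7 over the list alone) and NRF2 genes (9 of 11, 9 over the list alone). All these lists had camera calls that held with an estimated correlation. Fcgr1 was higher by 1.44 ± 0.11, Fcgr4 by 2.21 ± 0.10 and Fcgr3 by 0.66 ± 0.10, while Fcgr2b (-0.58 ± 0.12) and Ifngr1 (-1.18 ± 0.11) were lower. In total 1356 features were higher and 1922 lower (340 and 211 at least 2-fold), of which 452 and 843 had been called with neither stimulus alone. A call with both stimuli only is no departure from additivity. Among all features called with neither stimulus alone, 31 had a positive and 18 a negative interaction that passed its test. Cyclic loess gave 1614 higher and 1528 lower (51.4% higher against 41.4%), and centring on housekeeping genes 471 higher and 994 lower (1465 calls).

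**Figure D1:**
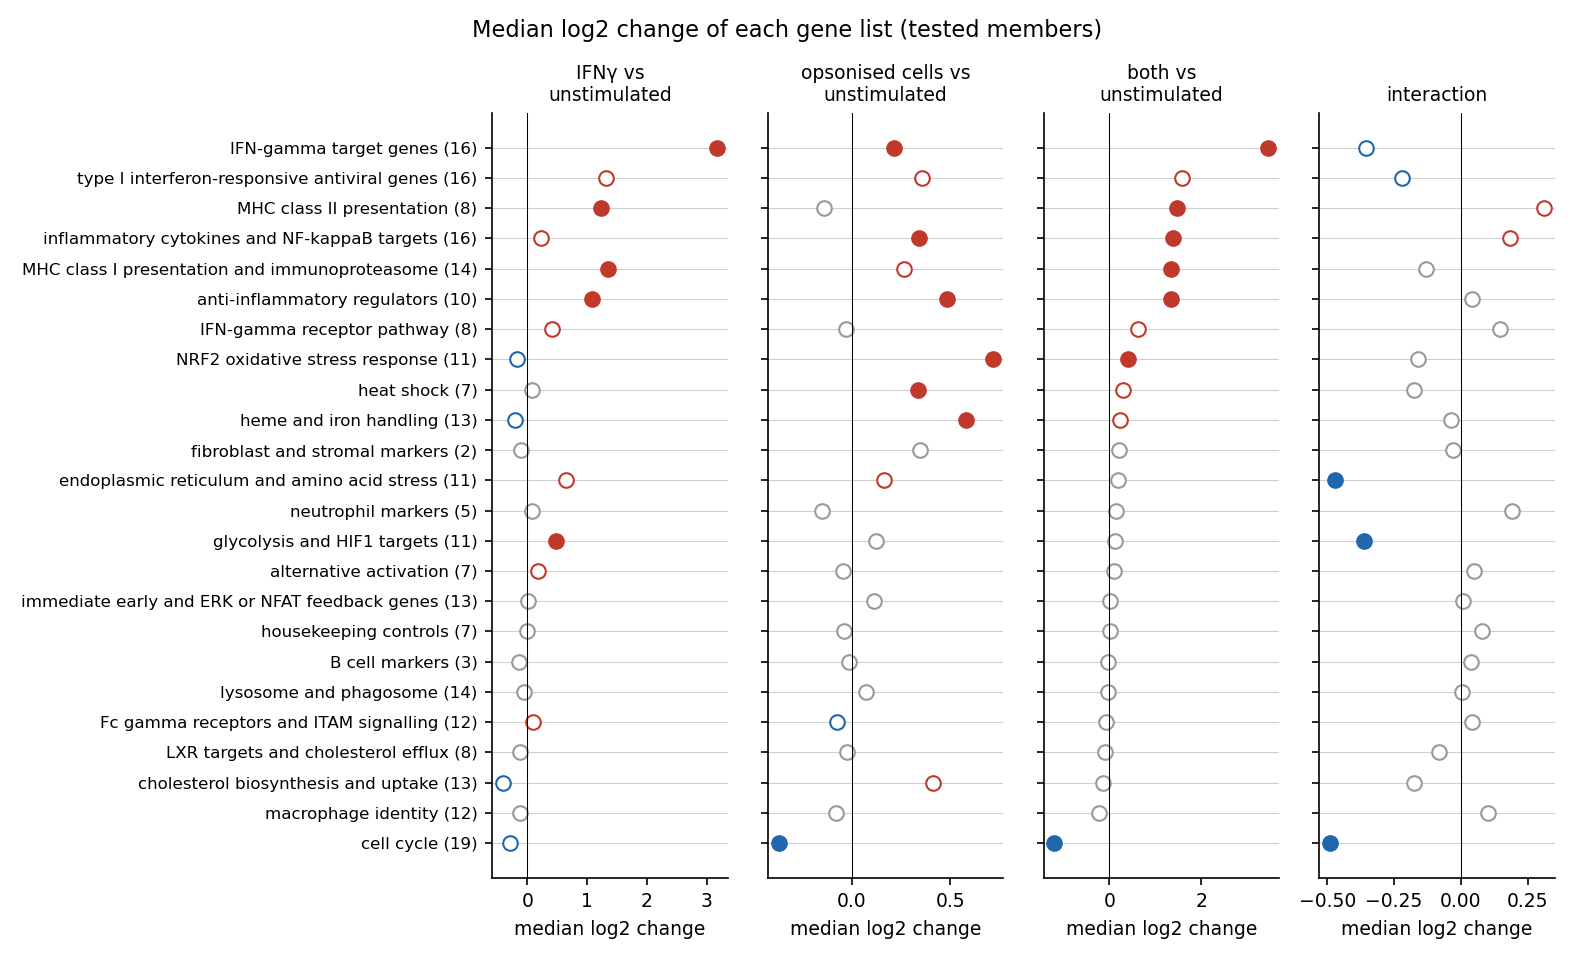
Median log2 change of the tested members of each gene list (number in brackets) for IFNγ, opsonised cells and both against unstimulated cells and for the interaction. Filled circles are lists called by camera with the preset and the estimated correlation, coloured open circles with the preset one alone, grey open circles not called; cell cycle medians are -0.37 with opsonised cells and -1.20 with both.

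Adding opsonised cells to IFNγ raised Hmox1 by 4.62 ± 0.10, Hspa1a at least 10.8-fold, and Ednrb by 3.57 ± 0.12 over IFNγ alone. Srxn1 (3.40 ± 0.12), Gclm (3.31 ± 0.12) and Slc40a1 (3.14 ± 0.09) rose as well. Tfrc fell by 2.55 ± 0.12, as did the replication-dependent histone genes H2ac15 (-1.51 ± 0.10) and H2ac12 (-1.48 ± 0.10). The DNA methylation maintenance gene Uhrf1 (-1.49 ± 0.14), Zfp36l1 (-1.48 ± 0.10) and the mismatch repair gene Msh6 (-1.36 ± 0.12) also fell. Of 16 inflammatory genes 13 rose (13 over the list alone; median 0.95), Cxcl2 at least 3.48-fold and Tnf by 1.11 ± 0.11. In turn 15 of 19 cell cycle genes fell (17 over the list alone; median -0.85). NRF2 genes (8 of 11 higher, 9 over the list alone), heme and iron genes (6 of 13 higher and 1 lower, 7 and 1 over the list alone) and anti-inflammatory regulators (6 of 10 higher, 6 higher and 1 lower over the list alone) rose. These 5 lists kept their calls with an estimated correlation. Fcgr1 (-0.81 ± 0.11), Fcgr2b (-0.70 ± 0.12) and Fcgr3 (-0.36 ± 0.10) fell, while Ciita (0.21 ± 0.12) did not pass the test, nor did Irf1 (-0.08 ± 0.10), where a signal ceiling may hide a change at intensities of 25710 with IFNγ and 24311 with both. Its 5 probes, the others dimmer on average, had similar ranges of change against unstimulated cells: 2.07 to 4.04 with IFNγ and 2.07 to 3.96 with both. In total 604 features were higher and 699 lower. This count of 1303 became 719 without IFNg replicate 1, 793 without IFNg replicate 2 and 279 after centring on housekeeping genes.

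Adding IFNγ to opsonised cells raised Cxcl9 by 7.22 ± 0.10, Cxcl10 by 5.56 ± 0.11, Upp1 by 5.14 ± 0.11, Cd40 by 5.06 ± 0.11, Calhm6 by 4.63 ± 0.11 and Batf2 by 4.38 ± 0.11. Lhfpl2 (-2.74 ± 0.10), Gsta3 (-2.44 ± 0.16), St6gal1 (-2.33 ± 0.13), Cd28 (-2.22 ± 0.13), Sla (-2.22 ± 0.12) and Idh1 (-1.79 ± 0.11) fell. All 8 MHC class II genes rose (8 over the list alone; median 1.51), Cd74 by 2.99 ± 0.12. Of 13 cholesterol biosynthesis genes 9 fell (12 over the list alone; median -0.55), the squalene epoxidase gene Sqle by 1.00 ± 0.11 and Hmgcs1 by 0.94 ± 0.09. This call held with an estimated correlation (adjusted p = 0.0425). Of 11 NRF2 genes 5 fell (7 over the list alone), Slc7a11 by 1.23 ± 0.12 and Srxn1 by 0.97 ± 0.12 (adjusted p = 0.0809 with an estimated correlation). Hmox1 was at -0.13 ± 0.10 without a call, at intensities where a ceiling may hide a change. In total 1059 features were higher and 1519 lower, and centring on housekeeping genes gave 318 higher and 1004 lower. Cyclic loess gave 1231 and 1193 (50.8% higher against 41.1%), so the excess of decreases depends on the scaling.

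The interaction asked where the combined response departed from the sum of the single log2 changes. The chemokine gene Ccl5 departed most, with an interaction of 2.74 ± 0.19 (adjusted p = 4.5e-09). Its mean intensity was 280 unstimulated, 689 with IFNγ, 307 with opsonised cells and 5046 with both. Positive interactions were also found for the adhesion molecule gene Vcam1 (1.78 ± 0.17), Slc40a1 (1.66 ± 0.13), the ubiquitin-like modifier gene Ubd (1.49 ± 0.16), and Klhl6 (1.48 ± 0.16). They were also found for Cst7, which encodes cystatin F (1.22 ± 0.18), Hmox1 (1.21 ± 0.14) and Ednrb (1.20 ± 0.17). Nos2 (adjusted p = 1.3e-05) and the antiviral gene Oasl1 passed as well, without a size here, since unstimulated macrophages, and for Nos2 also those given opsonised cells alone, were not above background. Vcam1 and Ubd lay close to the floor of 200.1 in every group but that with both stimuli. Their single arrays there read 178.2 to 221.3 and 199.3 to 218.6, so the sizes of their interactions are uncertain. Hmox1 and Slc40a1 were lowered by IFNγ alone, and with opsonised cells they stood at 70.5% and 73.3% of the highest intensity on the arrays. Negative interactions were largest for Gsta3 (-2.09 ± 0.23), the collagenase gene Mmp13 (-2.01 ± 0.16), the acetyl-CoA synthetase gene Acss2 (-1.55 ± 0.16), and Chac1 (-1.50 ± 0.17). Then came Ifit2 (-1.33 ± 0.17), the amino acid transporter gene Slc7a5 (-1.32 ± 0.19), Ifit3 (-1.30 ± 0.18), Dnmt3l (-1.26 ± 0.16), Cdca7 (-1.23 ± 0.18) and Gbp2 (-1.18 ± 0.14). Another Gbp2 probe gave 0.19, among 3 whose rise with IFNγ ranged from 0.52 to 5.36. The weakest probe gave -0.08 for Mmp13, -0.55 for Ifit3, -0.75 for Ifit2 and 0.62 for Ednrb. With IFNγ alone Gsta3 (215.8 and 204) and Dnmt3l (215.4 and 198.4) lay close to the floor of 200.1. This can make the effect of opsonised cells in the presence of IFNγ look smaller, so the sizes of their negative interactions are uncertain.

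Cell cycle genes had a median interaction of -0.49 (3 of 19 called negative, 11 over the list alone; camera adjusted p = 6.4e-09). Medians were -0.47 for endoplasmic reticulum and amino acid stress genes (5 of 11, 8 over the list alone) and -0.36 for glycolysis genes (2 of 11, 5 over the list alone). These 3 lists kept their calls with an estimated correlation. Among the stress genes the asparagine synthetase gene Asns had an interaction of -1.11 ± 0.17 and was lower with both stimuli than with IFNγ (-0.86 ± 0.12). The inflammatory list had 4 positive interactions among 16 genes (5 positive and 1 negative over the list alone; adjusted p = 0.051 with an estimated correlation). MHC class II genes had 1 of 8, Cd74 at 1.03 ± 0.17 (3 over the list alone; adjusted p = 0.051 with an estimated correlation). IFNγ target genes had 4 negative interactions among 16 (3 positive and 8 negative over the list alone; adjusted p = 0.0826 with an estimated correlation), including Igtp (-0.84 ± 0.15) and Cxcl10 (-0.73 ± 0.16). Type I interferon-responsive genes had 1 positive and 2 negative among 16 (1 and 5 over the list alone; adjusted p = 0.436 with an estimated correlation). Interactions of the receptor genes Fcgr1 (-0.25 ± 0.15), Fcgr4 (0.34 ± 0.14) and Ifngr1 (0.30 ± 0.16) and of Tnf (-0.43 ± 0.16) and Cxcl9 did not pass the test. Of these, Fcgr4 and Cxcl9 were bright enough with both stimuli for a ceiling to hide a difference. Cxcl9 is given without a size, since it was not above background in unstimulated cells.

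In total 104 features had a positive and 122 a negative interaction, and on the linear intensity scale 102 and 116 kept that sign. In 23 and 11 of them at least 1 group was not above background. Of the positive ones 2 were raised by both single stimuli and 31 were called with neither. Another 46 were lowered by at least 1 single stimulus, 16 of them by both, so a positive interaction can also be a fall smaller than the sum of the single changes. Of the negative ones 34 were raised by both single stimuli, 20 by IFNγ alone and 32 by opsonised cells alone. The count of 226 became 17 after centring on housekeeping genes. It was 137 and 103 without unstimulated replicate 1 and without unstimulated replicate 2, and 101 and 127 without IFNg replicate 1 and without IFNg replicate 2. Across all genes the effect of opsonised cells without IFNγ correlated with that in its presence at r = 0.623 (Spearman 0.435), 2 contrasts that share no array, for which simulated unchanged groups gave at most 0.0285.

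**Figure D2:**
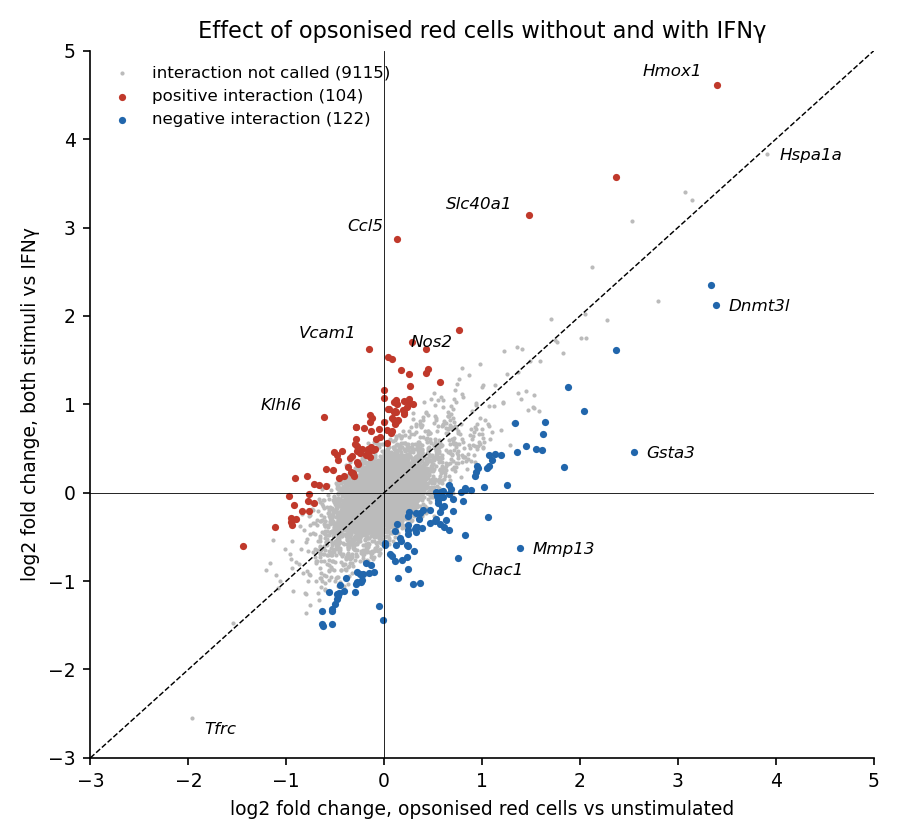
Log2 fold change made by opsonised red cells without IFNγ (horizontal) and in its presence (vertical), 1 point per feature, with equal effects on the dashed line. Red and blue points are the 104 positive and 122 negative interactions. Ccl5 lies near 0 on the horizontal axis and at 2.87 on the vertical axis, while Hspa1a lies close to the line. Hspa1a was not above background in unstimulated cells or with IFNγ, so its place does not show equal effects.

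Above both single stimuli stood 261 features, led by Ccl5 (2.87 ± 0.13 over IFNγ and 4.04 ± 0.13 over opsonised cells) and Oasl1 (1.71 ± 0.13 and 1.92 ± 0.13). Next were Vcam1 (1.63 ± 0.12 and 1.70 ± 0.12), and Ubd (1.53 ± 0.11 and 1.59 ± 0.11), then Nos2 (1.51 ± 0.12 over IFNγ and at least 3.41-fold over opsonised cells) and the NF-κB inhibitor gene Nfkbie (1.41 ± 0.13 and 1.88 ± 0.13). With either single stimulus Vcam1 and Ubd lay near the background floor, so the sizes of their changes may be understated. Of these 261, 65 had a positive interaction, 3 a negative one and 193 none that passed, Nfkbie among them (0.61 ± 0.19, adjusted p = 0.091). Below both stood 386 features, led by the cytokinesis gene Anln (-1.31 ± 0.11 against IFNγ and -1.39 ± 0.11 against opsonised cells), and Cdca7 (-1.28 ± 0.13 and -1.22 ± 0.13). They were followed by H2ac15 (-1.51 ± 0.10 and -1.21 ± 0.10), H2ac12 (-1.48 ± 0.10 and -1.21 ± 0.10), Cdc20 (-1.13 ± 0.12 and -1.17 ± 0.12) and the ceramide kinase gene Cerk (-1.12 ± 0.10 and -1.39 ± 0.10). Of these 386, 38 had a negative interaction and 1 a positive one. The sum of 647 became 382 without IFNg replicate 1, 413 without IFNg replicate 2 and 151 after centring on housekeeping genes.

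**Figure D3:**
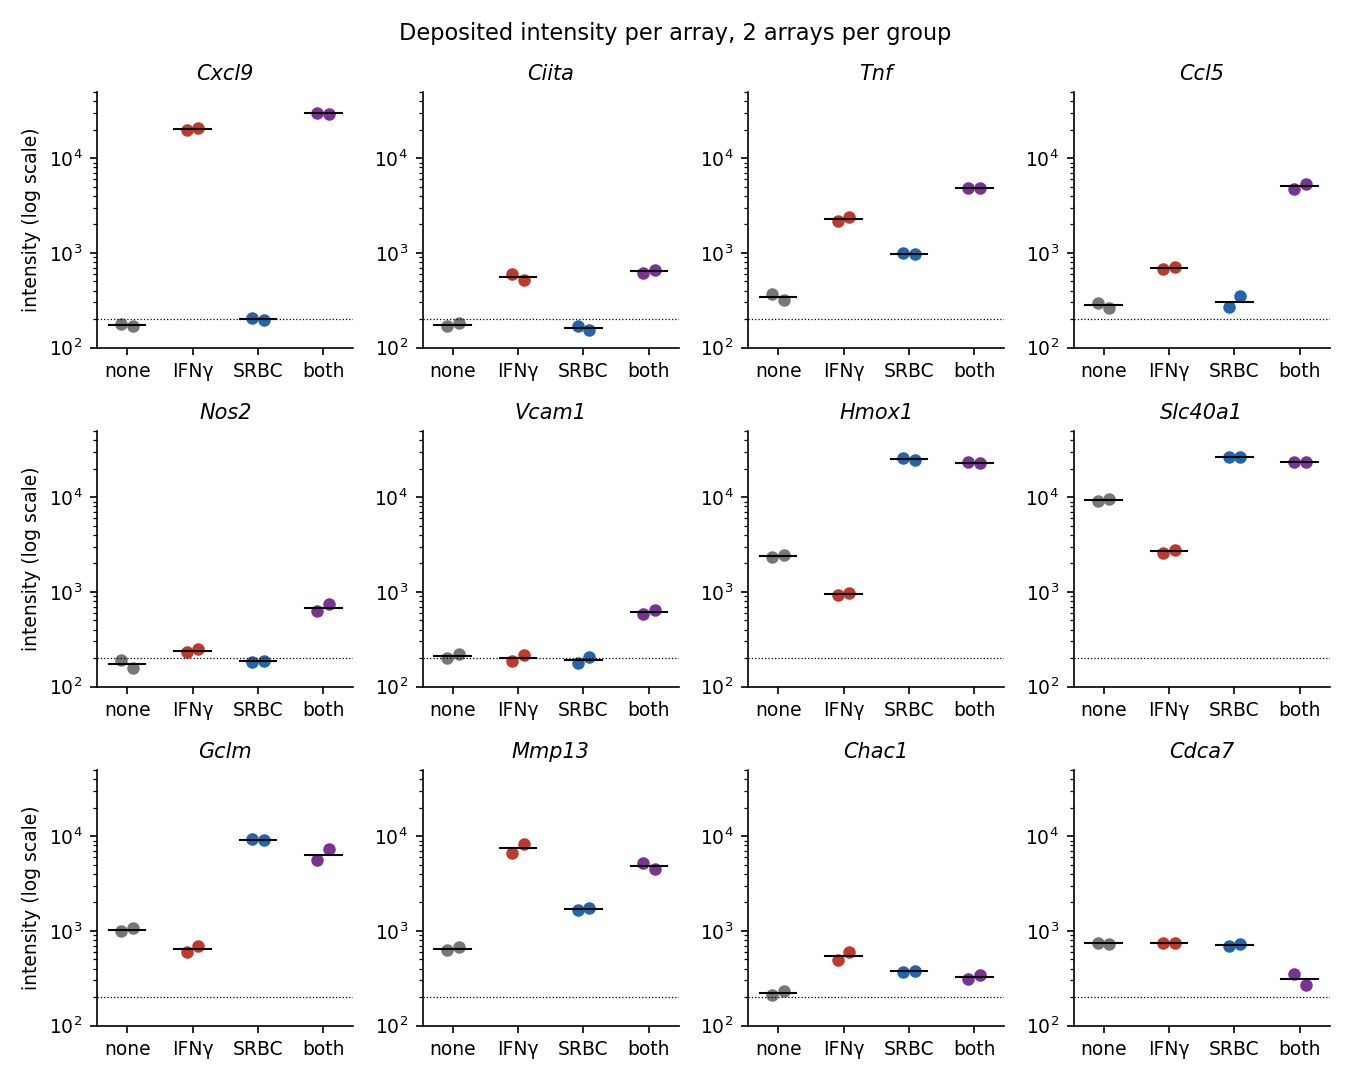
Deposited intensity of 12 named genes on each array (log axis; 1 point per array, bars are group means of log2 values, 2 arrays per group) in unstimulated cells and with IFNγ, opsonised red cells (SRBC) or both. The dotted line is the background floor of 200.1; Nos2 and Vcam1 rise clear of it with both stimuli, and Cdca7 drops with both.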

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

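Among the explanations weighed here, the tests of background, of linear additivity, of a smaller response of IFNγ targets in general and of the ceiling for Hmox1 and Slc40a1 and for bright genes lower with both stimuli than with IFNγ were chosen only after the results they bear on had been seen. What drew attention was the test of whether the effect of opsonised cells differs without and with IFNγ. It passed for 226 features, and for 13 of them the effect had opposite, called signs in the 2 states. The largest log2 differences were those of Ccl5 (2.74), Vcam1 (1.78), Slc40a1 (1.66), Ubd (1.49), Klhl6 (1.48), Nos2 (1.43), Oasl1 (1.43), Cst7 (1.22), Hmox1 (1.21) and Ednrb (1.20) above additivity. Below it were Gsta3 (-2.09), Mmp13 (-2.01), Acss2 (-1.55), Chac1 (-1.50), Ifit2 (-1.33), Slc7a5 (-1.32), Ifit3 (-1.30), Dnmt3l (-1.26), Cdca7 (-1.23) and Gbp2 (-1.18). Nos2 was not above background in unstimulated cells or with opsonised cells alone, and Oasl1 in unstimulated cells, so their values are fitted numbers without a known size. The sizes for Vcam1 and Ubd are uncertain as well, since both lay near the floor in every group but that with both stimuli. So are those for Gsta3 and Dnmt3l, which lay near the floor with IFNγ alone. Median differences of gene lists that passed camera were -0.49 for cell cycle, -0.47 for endoplasmic reticulum and amino acid stress, -0.36 for glycolysis and HIF1 targets, -0.36 for IFNγ targets, -0.22 for type I interferon-responsive genes, 0.31 for MHC class II and 0.18 for inflammatory genes, of which the last 4 were lost with an estimated correlation (adjusted p = 0.0826, 0.436, 0.051 and 0.051).

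The 104 features above additivity include genes such as Nos2 that were near background with a single stimulus, so background left in the signal could hide part of the single responses. After normexp background correction 84 of the 104 kept a positive, called interaction. For the other 20 the median went from 0.68 to 0.92 and its median standard error from 0.16 to 0.31, so the calls ended with the larger spread and not with a smaller difference. Normexp enlarged the interaction of 102 of the 104. It cannot recover a response lost at background, and in 23 of the 104 at least 1 group was not above background. The background was also modelled and not measured, so background stays open as an explanation. It was weighed here only for the features above additivity. A signal ceiling needs bright probes, and 6 of the 104 had a group mean above 25% of the highest intensity. For Hmox1 and Slc40a1, whose means with opsonised cells were 70.5% and 73.3% of the highest intensity, and which have no further tested probe, a ceiling and a true difference cannot be told apart.

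IFNγ raised 54 features that fell short of additivity with both stimuli, and a ceiling could account for bright genes such as Gbp2, Cxcl10 and Cd274, since 8 of the 54 had a group mean above 25% of the highest intensity. A ceiling flattens the highest level and makes no fall. It is therefore argued against for Ccnd1 (-1.13 ± 0.12) and Igtp (-0.32 ± 0.11), the 2 of the 8 called lower with both stimuli than with IFNγ. That call itself picked them out, so it is no separate test. The other 6 were not called lower, and for them a ceiling and a true shortfall cannot be told apart. Among these a further, on average dimmer Gbp3 probe gave an interaction of -0.665, against -0.58 on the probe used, while another Gbp2 probe gave 0.19. The 3 Gbp2 probes ranged from 0.52 to 5.36 with IFNγ. A weakly responding probe can show little shortfall, so the Gbp2 value decides nothing about a ceiling. Responses that add on the linear scale would leave no linear shortfall, yet 47 of the 54 lay below 0 by more than 2 standard errors. Choosing the 54 by a negative log2 interaction on the same arrays tilts this count upwards, and the standard errors rest on 2 arrays per group. Of 16 tested IFNγ target genes 2 were lower with both stimuli than with IFNγ, which decides nothing about a general loss of the IFNγ response, since opsonised cells alone raised 6 of them; 15 were still higher with both stimuli than with opsonised cells. Called negative interactions of 4 of the 16 leave open whether the shortfall is a smaller IFNγ response in general, limited to some genes or partly a ceiling. These 4 are all among the 8 bright features: Gbp2, Cxcl10, Igtp and Gbp3, at 80.6%, 59.1%, 35.2% and 26.6% of the highest intensity. Of them only Igtp was called lower with both stimuli than with IFNγ.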

How the results depend on the processing

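Of the analyses set out beforehand, neqc, median scaling after normexp and filters on detection p-values were not run, and the values without background correction and the authors' value table are the main values themselves. Normexp on the deposited intensities, other floors, cyclic loess, housekeeping centring and the split of the control arrays were chosen after seeing the data. No named gene and no list test reversed direction in any of them as a call, although the median of the Fcγ receptor list with opsonised cells went from -0.08 to 0.02 after housekeeping centring, and that with both stimuli against opsonised cells from 0.03 to -0.20. The counts of called features in the 6 comparisons (2037, 1141, 3278, 1303, 2578 and 226, in the order IFNγ, opsonised cells and both against unstimulated, both against IFNγ, both against opsonised cells, interaction) and of features beyond both single stimuli (647) stayed within 1.5 times with no filter, other floors, every probe, no trend, array weights, normexp and cyclic loess, and, for the 5 comparisons of groups and the features beyond both, with the groups compared alone. After normexp with offset 16 log2 changes of called features grew by median factors of 1.16 to 1.23, an estimate that depends on this model and its offset, since no background was measured. Replicate numbers did not pair the arrays: deviations from group means of same-numbered arrays correlated at -0.039 to 0.045 over 6 pairs of groups, and with the replicate block the counts were 2003, 1082, 3264, 1283, 2544, 217 and 644.

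At least a 2-fold change left 318, 87, 551, 118, 351, 37 and 41 features, by construction. An adjusted p under 0.01 left 1354, 670, 781, 101 and 383 for IFNγ, opsonised cells, both against IFNγ, interaction and beyond both. Centring on housekeeping genes left 652, 216, 1465, 279, 1322, 17 and 151, and moved the median log2 change of all genes by 0.10 for opsonised cells, -0.13 for both, -0.23 for both against opsonised cells and -0.14 for the interaction. The housekeeping shift itself was 0.08 and -0.34 on the 2 arrays with opsonised cells, which adds spread within groups. Under it 123 of 458 named values lost their call, among the 20 largest interactions those of Nos2 (fitted log2 1.43 before and 1.29 after), Oasl1 (1.43 and 1.28), Cst7 (1.22 and 1.07), Hmox1 (1.21 and 1.07) and Ednrb (1.20 and 1.06), which moved by the common shift of -0.14. Leaving out each array in turn, with the lone array assumed to vary like the other groups, gave 1291 to 2113 calls for IFNγ, 642 to 1158 for opsonised cells, 2509 to 3355 for both, 719 to 1384 for both against IFNγ, 2041 to 2443 for both against opsonised cells, 101 to 239 for the interaction and 382 to 607 beyond both; fewer samples raise the standard errors of the group that lost an array. Of 144 list tests 69 were called, 34 with an estimated correlation, 95 with fry and 64 after housekeeping centring. The correlation of the IFNγ and opsonised cell effects was 0.262 with no filter and 0.276 after normexp, and that of the opsonised cell effects without and with IFNγ was 0.563 and 0.536; the cause was not tested.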

Other observations

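In this part the tests were set out before the values they measure were seen, while the genes with opposite effects were singled out afterwards. Of 14 lysosome and phagosome genes 4 fell with IFNγ (4 adjusted over the list alone), Lipa by 0.58 ± 0.13, and 2 rose with opsonised cells (2 over the list alone), Lipa by 0.47 ± 0.13 and Atp6v1h by 0.44 ± 0.10. Of 8 LXR targets 3 rose with opsonised cells (3 higher and 1 lower over the list alone), including Nr1h3 (0.66 ± 0.12), while Abcg1 rose with IFNγ (0.88 ± 0.12). Of 7 tested alternative activation genes 3 rose and 1 fell with IFNγ (3 and 1 over the list alone), with the lectin genes Mgl2 at 1.26 ± 0.12 and Mrc1 at -0.30 ± 0.10 (adjusted p = 0.163 with an estimated correlation). Of 12 macrophage identity genes 3 fell and 1 rose with IFNγ (5 and 3 over the list alone), with the fractalkine receptor gene Cx3cr1 at -1.52 ± 0.13 and the lipopolysaccharide coreceptor gene Cd14 at -1.29 ± 0.10. Of 13 immediate early and feedback genes 4 rose and 2 fell with IFNγ (4 and 4 over the list alone), with Dusp6 at -1.56 ± 0.12. With the red cells 2 rose (2 over the list alone), Dusp4 by 1.13 ± 0.13 and Ier3 by 0.66 ± 0.11. Of 7 housekeeping controls 1 rose and 1 fell with IFNγ (1 and 1 over the list alone), with Hprt at 0.74 ± 0.13 and Rpl13a at -0.53 ± 0.11. None passed with opsonised cells.

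Markers of other cell types were mostly dim. Tested were 5 of 11 neutrophil markers on the array, 3 of 7 B cell markers, 2 of 9 fibroblast markers, 1 of 6 erythroid markers (Rhag), 1 of 8 dendritic cell markers (Clec9a), 1 of 7 mast cell and basophil markers (Cpa3) and 0 of 11 T and NK cell markers. With IFNγ 0 neutrophil, B cell and fibroblast markers passed, also adjusted over each list alone. With opsonised cells the neutrophil gene S100a9 fell by 0.39 ± 0.13 (1 over the list alone), 0 B cell markers passed, and Acta2 rose by 0.72 ± 0.12 (1 of 2, 1 over the list alone), although another Acta2 probe gave -0.05. With both stimuli 2 of 5 neutrophil markers were higher than in unstimulated cells (2 over the list alone), S100a8 by 0.39 ± 0.13 and S100a9 by 0.35 ± 0.13, and 2 of 5 were higher than with opsonised cells (2 over the list alone), S100a8 by 0.54 ± 0.13 and S100a9 by 0.74 ± 0.13. Cd79b, 1 of 3 B cell markers, was lower than with IFNγ (-0.41 ± 0.12; 1 over the list alone). Acta2 with both stimuli was higher than in unstimulated cells (0.32 ± 0.12) and than with IFNγ (0.56 ± 0.12), and lower than with opsonised cells (-0.40 ± 0.12), while another probe gave -0.06 in the first and 0.09 in the last of these. S100a8 was the brightest of the neutrophil markers, at 1911 in unstimulated cells and 2498 with both stimuli.

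The effect of opsonised cells had opposite, called signs without and with IFNγ for 13 features, with the interaction called as well. Mmp13 went from 1.38 ± 0.12 to -0.63 ± 0.12, Chac1 from 0.76 ± 0.12 to -0.74 ± 0.12 and Ifit3 from 0.83 ± 0.13 to -0.48 ± 0.13. Over the 3 Mmp13 probes the effect ranged from 0.08 to 1.38 without IFNγ and from -0.63 to -0.0015 in its presence, so not every probe showed the reversal. The change with IFNγ alone ranged from 0.23 to 3.52 over these probes, and a weakly responding probe could hardly show a reversal. In the other direction Klhl6 went from -0.62 ± 0.12 to 0.86 ± 0.12 and Mertk, a receptor gene for uptake of dying cells, from -0.51 ± 0.11 to 0.46 ± 0.11.

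Genes raised by opsonised cells could in part reflect RNA carried over from the red cells. Red cell RNA would bring globin transcripts above all. Over 4 globin and Alas2 probes the higher of the median log2 changes without and with IFNγ was 0.0179. Since 3 of the 4 were not above background, and mouse probes bind sheep transcripts to an unknown degree, this decides nothing and carry-over stays open. The direction of the response was largely shared between IFNγ states: of 76 features raised at least 2-fold without IFNγ, 68 were higher with both stimuli than with IFNγ. Called interactions were negative for 24 and positive for 3 (Hmox1, Slc40a1 and Ednrb), a split that choosing features by a large effect without IFNγ tilts towards negative. Whether the rise of Hmox1, Spic and NRF2 genes follows from the red cells' heme or from Fcγ receptor signalling was not tested, since the design has no group with uncoated red cells or with IgG2a alone.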
